A study of Mus musculus with 15 samples.

How the data were processed

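Bulk RNA sequencing was measured in hematopoietic stem cells (HSCs) sorted from mouse bone marrow into TRIzol-LS. Per the labels' protocols, libraries were made with SMART-Seq v4 from 2 ng of total RNA. Per the labels, 15 samples fell into 3 groups of 5: young control mice of 3 months, aged control mice of 18 months and aged Thbs1 knockout mice of 18 months. The labels do not say that the 5 samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

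Per the submitters' processing notes, the tools used were FastQC 0.11.5, STAR and edgeR, and the genome build was GRCm38 (mm10); the notes give neither their order nor their settings. The authors deposited 1 table of FPKM values with 2 decimals for 20696 genes and 15 libraries. All 20696 gene identifiers were found in the GENCODE M21 annotation, which gave gene symbols, positions and lengths on GRCm38. No genome sequence was used. The settings of read counting, including strand, are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may be shared.

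The table has 2 header lines, 1 with library names that hold a letter, a sex and a number, and 1 with sample titles. GEO's own sample descriptions pair library names with titles in another way: for 5 columns both names point to the same sample and for 10 they point to different ones. Each column was assigned to a group by its title, and its sex and letter were read from its library name. This was decided without looking at expression values. With this assignment, the letters A, B and C coincide with the young control, aged control and aged Thbs1 knockout groups. The planned comparisons of letters with sex as a covariate were therefore comparisons of the groups with sex as a covariate. The young controls held 2 male and 3 female libraries, the aged controls 3 and 2, and the libraries labelled aged Thbs1 knockout 2 and 3. The labels give no sequencing batch or date.

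Depth was recovered from the rounding of the FPKM values. For genes of at most 250 nucleotides, all values were whole multiples of what 1 read is worth, within a tolerance of 0.1 reads, and at least 98.2% of values were in held-out genes of up to 500 nucleotides. The reads in genes came to 17.36e6 to 35.08e6. Their ratio to the library sizes recovered in this way lay between 0.898 and 1.038.

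Values were analysed as log2(FPKM + 1). A log2 change on this scale understates the change of genes with low FPKM. The 11345 genes with a mean FPKM of at least 1 over all libraries were tested, and 9351 were not. Groups were compared with limma 3.58.1 (linear models with an intensity-dependent prior variance, in R 4.3.3), with all 15 libraries in 1 fit and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and every adjusted p for a gene comes from this limma fit unless another is named. All limma tests were two-sided. The planned comparison of female with male libraries used sex alone. Thbs1 was also compared with exact two-sided permutation tests between groups of 5, and with a two-sided permutation test between sexes. Count-based tests were not used on these values, and voom was run on the recovered reads as an alternative.

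Gene lists were fixed before the data were examined, as were the 3 comparisons of groups, the tests and the rule for named genes. Some single genes are not reported here. The 26 lists cover HSC aging (genes higher with age), lymphoid priming, HSC identity, megakaryocyte and platelet, interferon response, TNF and NF-kB response, immediate-early and dissociation stress, TGF-beta signaling and targets, thrombospondin receptors and relatives, cell cycle, oxidative phosphorylation, mitochondrially encoded, ribosomal proteins, p53 and DNA damage response, unfolded protein and integrated stress response, lysosome and autophagy, MHC class II, myeloid progenitor and neutrophil, erythroid, B cell, T and NK cell, endothelial and stromal, mast cell and basophil, macrophage and dendritic cell, Y-linked and X inactivation genes. The 22 lists with more than 1 tested member were tested with camera at a preset correlation of 0.01, giving 66 list tests adjusted together, and with an estimated correlation and with fry as alternatives. Camera compares a list with all other genes; fry does not.

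Named genes were chosen by a fixed rule. They were Thbs1, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean FPKM of at least 2 in the higher group, and called members among the 4 of each list with the smallest p. Genes known only by clone or model names, pseudogenes and sex-linked genes were left out of the ranking. Called genes within 5 Mb of Thbs1 were also named. Genes outside this rule are said to be chosen after their values were seen.

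The change with age was set against the change with the knockout label by a correlation across genes. The aged controls enter both, so unchanged groups against shared controls were simulated 100 times, and the aged controls were split into 2 and 3 libraries so that each comparison used its own. Nuclear copies of mitochondrial genes and parents of pseudogenes were sought among annotated transcripts with BLAST 2.17.0 at a word size of 16. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

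The analysis was tested on simulated data with the means and spread of the real libraries and 200 changed genes among 11345. For the comparison of aged with young controls, 25.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 100% of those changed 4-fold were recovered. For the libraries labelled knockout against aged controls these shares were 20.9%, 64.2% and 92.4%, and against young controls 20.9%, 64.2% and 100%. False calls made up 4.7%, 0.8% and 6.1% of calls in the same order. The simulated genes were drawn independently of each other, with no difference by sex or by library quality. These shares therefore do not carry over to the calls in the real libraries.

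Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at a mean FPKM of 5, median-of-ratios scaling, quantile normalization, robust eBayes, array weights, sex as a covariate, the replicate number as a block, only the 2 groups compared, and leaving out each library. Chosen after seeing the data were voom on recovered reads, groups by the library names in GEO's descriptions, leaving out replicates 2 and 5 of the libraries labelled knockout, the share of rRNA-like reads as a covariate, each sex alone by the table's library names, the list tests with each library left out, and an interaction of sex and group. The planned fits in each sex had assumed other numbers of libraries per group. The planned fits with the letter as a covariate, with sex and letter together, and with the title group added to the letter could not be made, because letter and group coincide.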

Results

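Gene expression was measured in sorted bone-marrow HSCs of mice in 3 groups of 5 libraries: young controls (3 months), aged controls (18 months) and libraries labelled aged Thbs1 knockout (18 months). The table held FPKM values of 20696 genes, of which 11345 were tested. Reads in genes ranged from 17.36e6 to 35.08e6 per library. Within groups, libraries correlated across genes at 0.97 to 0.987 in young controls, 0.953 to 0.988 in aged controls and 0.919 to 0.988 in the libraries labelled aged Thbs1 knockout. Of the reads, rRNA-like genes took 3.07% in replicate 2 and 1.97% in replicate 5 of the labelled knockout libraries, against 0.62% to 1.58% in the other libraries. Replicate 2 also had the highest share of mitochondrial reads (1.64%) and the lowest of protein-coding genes (93.61%). The first principal component held 38.8% of the variance, and its r squared was 0.64 with the share of rRNA-like reads, 0.4 with group and 0.27 with sex.

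Thbs1 (ENSMUSG00000040152, GRCm38 chromosome 2, 118111876 to 118127133) encodes thrombospondin 1, a matrix glycoprotein, and is the gene named in the knockout label. Its FPKM was 0.76, 0.70, 13.38, 2.42 and 3.95 in young controls 1 to 5, 0.20, 0.01, 0.62, 8.75 and 4.90 in aged controls 1 to 5, and 2.53, 1.69, 17.89, 12.69 and 17.25 in the libraries labelled aged Thbs1 knockout 1 to 5. The group means were 4.24 ± 5.28, 2.90 ± 3.84 and 10.4 ± 7.84 (SD, n = 5 each), so Thbs1 was not lower in the libraries labelled knockout. Their level lay above that of aged controls by 1.73 on the log2 scale (SE 0.71), which did not pass the test (limma adjusted p = 0.302; exact two-sided permutation p = 0.111, with 0.0079 the smallest possible for 5 against 5). With sex as a covariate the difference was 1.27 (limma adjusted p = 0.0377). Against young controls it was 1.19 (limma adjusted p = 0.324, exact permutation p = 0.19; with sex as a covariate, limma adjusted p = 0.0374). Aged and young controls differed by -0.54 (limma adjusted p = 0.676, exact permutation p = 0.548). When the columns were grouped instead by the library names in GEO's descriptions, the difference from aged controls was 1.38 (limma adjusted p = 0.437), again not a lower level. A value per gene does not show which exons the reads cover. Because Thbs1 went against the label, every direction given for these libraries is for libraries labelled aged Thbs1 knockout, not for a measured loss of Thbs1.

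Thbs1 differed between male and female libraries. In every group the males carried the lower replicate numbers, so a batch that followed these numbers cannot be told apart from sex. Thbs1 averaged 0.93 ± 0.885 FPKM (range 0.01 to 2.53) in 7 male libraries and 10.2 ± 6.04 (2.42 to 17.89) in 8 female libraries, a difference of 2.42 on the log2 scale (SE 0.36, limma adjusted p = 0.0038, permutation p = 0.0005). Sex-linked genes checked the library names. Xist, transcribed from the inactive X chromosome, lay at 2.5 to 5.81 FPKM in libraries named female and 0 to 0.02 in those named male. The Y-linked gene Eif2s3y lay at 2.12 to 5.72 in male and 0 to 0.04 in female libraries, and Ddx3y, Kdm5d and Uty parted the sexes in the same way. All 15 libraries matched the sex in the name that the table gives them. Neither Xist (adjusted p = 0.592) nor Eif2s3y (adjusted p = 0.767), the tested members of the X inactivation and Y-linked lists, changed between aged and young controls in the limma fit.

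**Figure D1:**
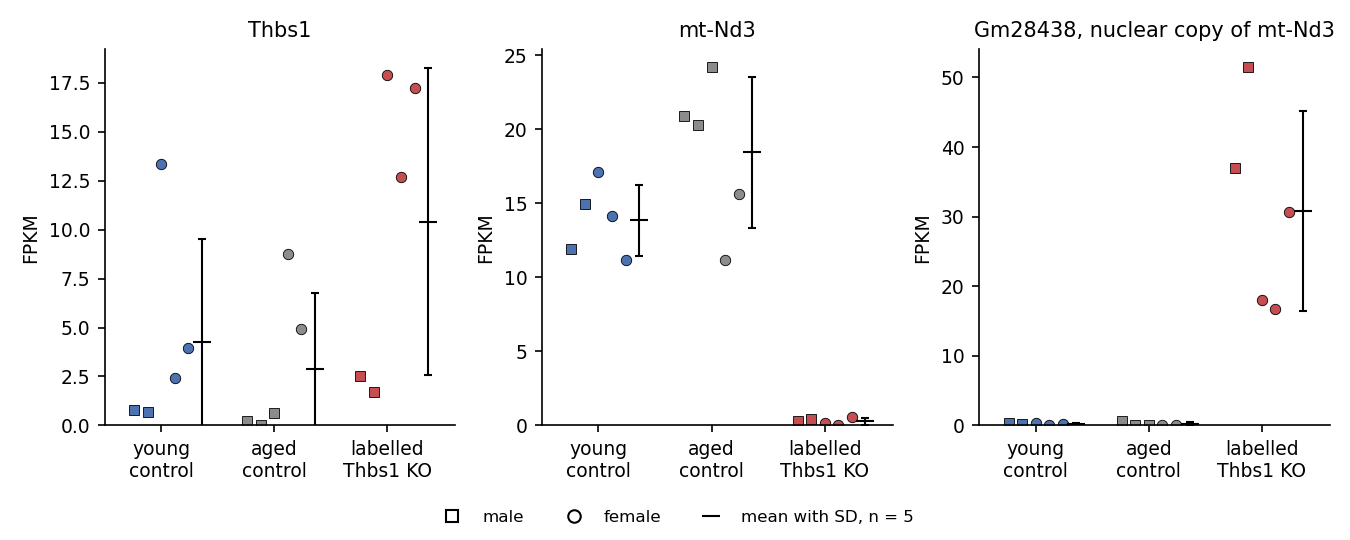
FPKM of Thbs1, mt-Nd3 and Gm28438, the nuclear copy of mt-Nd3, by group; squares are male and circles female libraries, and bars give the mean with SD (n = 5). Thbs1 reached 17.89 FPKM in a library labelled knockout, while mt-Nd3 lay at or under 0.59 in all 5 of these libraries and at or above 11.14 in the 10 controls.

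The first comparison asked how HSCs of aged control mice differed from those of young control mice. Clu, which encodes the secreted chaperone clusterin, rose from 18.0 ± 2.33 to 134 ± 23.6 FPKM (SD, n = 5 each; log2 change 2.83, SE 0.16, limma adjusted p = 1.16e-08). The tight-junction gene Cldn5 rose from 2.96 ± 0.409 to 64.6 ± 35.7 FPKM (log2 change 3.82, SE 0.36, adjusted p = 3.23e-06). Gpr183, an oxysterol receptor that guides immune cell migration, rose from 0.964 ± 0.279 to 26.2 ± 8.22 FPKM (log2 change 3.73, adjusted p = 1.42e-06). Rcvrn, a calcium sensor best known from photoreceptors, rose from 0.33 ± 0.156 to 13.7 ± 3.30 FPKM (log2 change 3.45, adjusted p = 1.6e-07). The other largest rises were Sbspon (3.46), Zg16 (3.46), Matn4 (3.04), Muc1 (2.98), Plscr2 (2.91) and Tmem215 (2.64 on the log2 scale). Among the largest falls, Ebi3, a subunit of interleukin-27 and interleukin-35, went from 44.9 ± 3.96 to 12.2 ± 0.561 FPKM (log2 change -1.80, SE 0.14, adjusted p = 3.52e-07). Flt3, the cytokine receptor that marks multipotent and lymphoid-primed progenitors, fell by 1.65 (adjusted p = 0.00043), and the lysosomal protease gene Ctss fell by 1.57 (adjusted p = 0.00111). The transcription factor gene Hnf4a fell by 1.58, the NADPH oxidase subunit gene Ncf4 by 1.73, Shisa8 by 2.00, Haao by 1.72, Kcnk12 by 1.55, Rnase6 by 1.54 and the platelet chemokine gene Ppbp by 1.49 on the log2 scale.

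The list of genes known to rise in aged HSCs moved most. Of its 32 tested members, 21 rose, none fell and 11 did not pass the test (28 rose when adjusted over the list alone), with a median log2 change of 1.32 (camera adjusted p = 9.52e-35, and 0.0217 with an estimated correlation). They included Clu, Gpr183, Nupr1 (2.55), which encodes a stress-induced chromatin protein, and the endocytic gene Ehd3 (2.05). Of 24 HSC identity genes, 6 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00711, and 0.0663 with an estimated correlation), among them Pdzk1ip1 (1.04), Procr, the surface marker gene Ly6a (0.88) and Mycn (0.81). Of 18 megakaryocyte and platelet genes, 3 of them shared with the aging list, 4 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0397, and 0.589 with an estimated correlation). Without aged control 5 the adjusted p of this list was 0.313, without young controls 2 and 4 it was 0.0704 and 0.0516. P-selectin (Selp, 2.58) and von Willebrand factor (Vwf, 1.82) rose, as did Gp1bb (1.09), while Ppbp fell. Of 21 TNF and NF-kB response genes, 5 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.074), with Socs3 (2.49), a feedback inhibitor of cytokine signaling, and the NF-kB cofactor gene Bcl3 (1.38) in front, followed by Ier3 (0.75) and Tnfaip2 (0.70). Of 38 interferon response genes, 4 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.01, and 0.623 with an estimated correlation): Rtp4 (0.99), Ifitm3 (0.75), Lgals3bp (0.54) and Oas1a (0.46). Without aged control 5 the adjusted p of the interferon list was 0.172; its mean log2(FPKM + 1) was 4.64 in aged control 5 and 4.32 in aged control 4, and 4.15 in each of aged controls 1 to 3, within the 3.99 to 4.21 of young controls. Of 9 MHC class II genes, H2-Eb1 (1.42) rose and 8 did not pass the test (5 rose adjusted over the list alone; camera adjusted p = 0.000726, and 0.572 with an estimated correlation).

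The cell cycle list ranked lower with age by camera at its preset correlation. Of 34 cell cycle genes, only Cdk1, the mitotic kinase gene, passed the test (log2 change -0.66), and 14 fell when adjusted over the list alone (median -0.56, camera adjusted p = 1.43e-08, and 0.524 with an estimated correlation). The mean log2(FPKM + 1) of this list was 4.82 in aged control 5, above the 4.56 to 4.73 of young controls, and 3.83 to 4.12 in the other aged controls. Of 14 genes of the p53 and DNA damage list, Cdkn1a (0.93) and Phlda3 (0.70) rose while the checkpoint gene Chek1 (-0.81) fell (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.316). Among 19 TGF-beta genes, Bmp4 (1.64), Id2 (1.45) and Cdkn1a rose (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.299). Among 10 thrombospondin receptors and relatives, the integrin gene Itgb3 (1.86) and the syndecan gene Sdc4 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.533). The lymphoid priming list held 1 gene that fell, Flt3, and 1 that rose, Cd53 (1.22), among 11 (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.253). The proteinase gene Prtn3 (1.49) of the myeloid list (camera adjusted p = 0.316) and the unfolded-protein regulator Xbp1 (0.57; list adjusted p = 0.502) rose, and the stress-induced phosphatase gene Dusp1 (-0.80) fell alone among 21 immediate-early genes (list adjusted p = 0.635). No member passed the test among 64 ribosomal protein genes (median 0.34, camera adjusted p = 5.93e-06, and 0.672 with an estimated correlation), 45 oxidative phosphorylation genes (0.0464, and 0.762 with an estimated correlation), 26 lysosome and autophagy genes (4 rose adjusted over the list alone; 0.0435, and 0.572 with an estimated correlation) and 9 mitochondrially encoded genes (0.379). The oxidative phosphorylation list did not pass without young controls 1 and 5 (0.221 and 0.182) or aged controls 1, 2, 3 and 5 (0.0553, 0.0677, 0.159 and 0.169), each left out alone, nor the lysosome list without young control 1 (0.0688) or aged controls 1, 2 and 4 (0.0553, 0.0577 and 0.0976). With sex as a covariate the oxidative phosphorylation list did not pass either (camera adjusted p = 0.0938). Erythroid (adjusted p = 0.979), B cell (0.185), endothelial and stromal (0.744) and mast cell and basophil (0.338) lists did not pass the camera test. Nkg7, the tested member of the T and NK cell list, did not change (log2 0.26, adjusted p = 0.603), nor did Cd68 of the macrophage and dendritic cell list (log2 -0.10, adjusted p = 0.756). Median and mean differed in sign for the immediate-early (0.02 and -0.11) and thrombospondin (-0.25 and 0.14) lists, and the erythroid list was ranked upward by camera with a median of -0.14.

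In all, 361 genes rose and 140 fell with age (501 of 11345, 4.42%), of which 207 changed at least 2-fold. With sex as a covariate, 423 rose and 202 fell; this is also the comparison of letter B with letter A. The count was 931 without aged control 5, 332 without young control 1, 324 without young control 3, and 302, 312 and 307 without aged controls 1, 2 and 3. Of 50 named calls, 37 held whichever library was left out; 13 were lost in at least 1 omission, most often Ifitm3, Cdk1, Phlda3, Sdc4 and Dusp1.

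**Figure D2:**
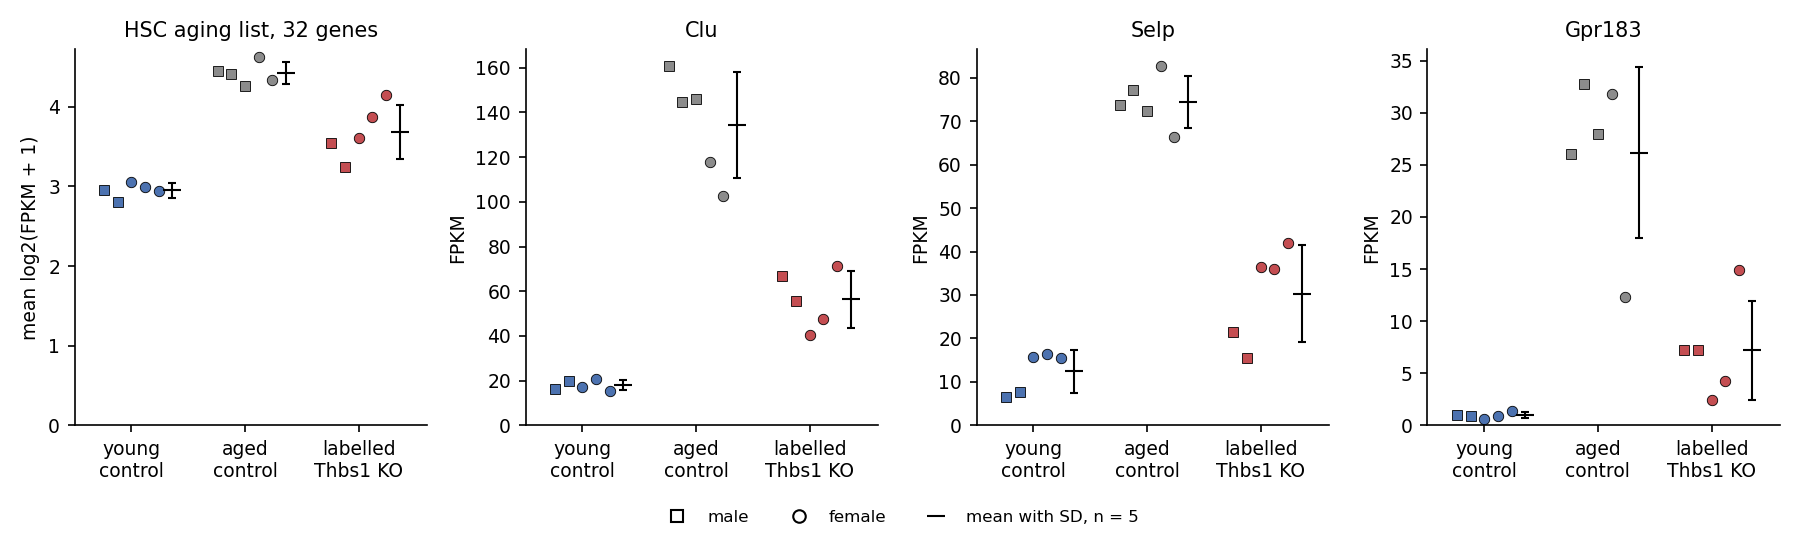
Mean log2(FPKM + 1) over 32 genes of the HSC aging list and FPKM of Clu, Selp and Gpr183 by group; squares are male and circles female libraries, and bars give the mean with SD (n = 5). Clu averaged 18.0 FPKM in young controls, 134 in aged controls and 56.4 in the libraries labelled knockout.

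The second comparison set the libraries labelled aged Thbs1 knockout against aged controls, to ask what changed in aged HSCs under the knockout label; Thbs1 itself was not lower in them. Several of the genes that rose most with age were lower. Rcvrn fell from 13.7 ± 3.30 to 1.98 ± 1.38 FPKM (SD, n = 5 each; log2 change -2.39, SE 0.25, limma adjusted p = 1.89e-05). Muc1, a membrane mucin, fell from 15.4 ± 6.62 to 2.73 ± 2.66 FPKM (log2 change -2.30, adjusted p = 0.000807). Gpr183 fell from 26.2 ± 8.22 to 7.20 ± 4.75 FPKM (log2 change -1.84, adjusted p = 0.00362), and Clu from 134 ± 23.6 to 56.4 ± 12.9 FPKM (log2 change -1.25). The platelet integrin gene Itga2b fell by 1.79 (adjusted p = 0.00101). The extracellular matrix genes Tgfbi (-1.84) and Col18a1 (-1.83) fell too, as did Tmem215 (-2.20). The calcium-binding gene Kcnip3 (-1.96) and Prom2 (-1.90), which neighbour each other on chromosome 2 at 9.37 and 9.41 Mb from Thbs1, also fell. The largest fall was that of the mitochondrial gene mt-Nd3, from 18.4 ± 5.08 to 0.29 ± 0.233 FPKM (log2 change -3.89, SE 0.19, adjusted p = 4.88e-10). It is uncertain as a fall of this gene, since the sum of mt-Nd3 and its near-identical nuclear copy Gm28438 did not fall (18.6 ± 5.14 and 31.1 ± 14.5 FPKM). Of the genes that rose, Tmem87a, a Golgi membrane protein gene, went from 0.588 ± 0.0432 to 5.81 ± 1.74 FPKM (log2 change 2.06, SE 0.18, adjusted p = 1.46e-06). Ebi3 rose from 12.2 ± 0.561 to 28.1 ± 6.45 FPKM (log2 change 1.12, adjusted p = 0.00018) and the membrane-binding gene Anxa6 by 1.48 (adjusted p = 0.00146). Cytl1 (1.51), Dupd1 (1.37), the zinc-finger gene Insm1 (1.21), the creatine synthesis gene Gatm (1.14), Snhg1 (1.01), the NADPH oxidase subunit gene Ncf1 (0.98) and the nucleolar gene Gnl3 (0.88) rose on the log2 scale.

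Of the 32 HSC aging genes, 10 fell, none rose and 22 did not pass the test in the libraries labelled knockout (18 fell adjusted over the list alone; median -0.57, camera adjusted p = 1.1e-16, and adjusted p = 0.0663 with an estimated correlation). Ehd3 (-1.42), Clu, Itga2b and the phospholipid scramblase gene Plscr2 (-1.70) were among them. Of 18 megakaryocyte and platelet genes, 4 fell and none rose (9 and 0 adjusted over the list alone; median -0.46, camera adjusted p = 3.68e-08, and adjusted p = 0.0663 with an estimated correlation): Itga2b, Selp (-1.35), Vwf (-1.21) and Gp1bb (-1.19). Among 24 HSC identity genes Mycn (-1.45) and Ly6a (-1.12) fell (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0233, 0.0836 with an estimated correlation and 0.0974 without aged control 4). Inflammatory lists were lower. Of 38 interferon response genes, 3 fell (10 adjusted over the list alone; camera adjusted p = 1.28e-06, and 0.41 with an estimated correlation), among them the GTPase gene Igtp (-0.92), Rtp4 (-0.82) and Oas1a (-0.50). Of 21 TNF and NF-kB response genes, Socs3 (-1.75), Bcl3 (-1.19) and Tnfaip2 (-0.61) fell (5 adjusted over the list alone; camera adjusted p = 0.00185, and 0.0601 with an estimated correlation). Of 19 unfolded protein genes, the endoplasmic-reticulum chaperone genes Sdf2l1 (-0.88), Pdia4 (-0.71) and Calr (-0.51) fell (5 adjusted over the list alone; camera adjusted p = 0.0588), and Itgb3 (-1.04) and Calr fell among 10 thrombospondin receptors and relatives (camera adjusted p = 0.316). The lymphoid genes Cd53 (-1.61) and Il2rg (-0.65) fell among 11 (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.138). The granulocyte receptor gene Csf3r (-1.01) fell among 9 myeloid genes (camera adjusted p = 0.318).

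No ribosomal protein gene passed the test, but the list lay higher (median 0.41, or 0.26 with quantile normalization; camera adjusted p = 6.23e-16, and 0.589 with an estimated correlation). This rested on the libraries with most rRNA-like reads: without replicates 2 and 5 of the labelled knockout libraries the adjusted p was 0.981. Without both, the aging list kept its fall (15 fell, camera adjusted p = 4.62e-23), as did the platelet (3.09e-07), interferon (1.17e-07), TNF (0.00148) and HSC identity (0.0222) lists. Lysosome (0.0397, and 0.572 with an estimated correlation) and MHC class II genes (0.0346, and 0.623 with an estimated correlation) lay lower with no member past the test. Without both replicates these were 0.0587 and 0.00151. With sex as a covariate the camera adjusted p was 0.0291 and 0.11, so the MHC class II call was lost there. Left out 1 at a time, aged controls 1 to 4 (0.0559, 0.0808, 0.0505 and 0.0867) and replicates 1 to 3 of the labelled knockout libraries (0.0502, 0.0876 and 0.0899) ended the lysosome call, and aged controls 1 to 3 (0.0553, 0.082 and 0.275) and replicates 3 and 4 (0.101 and 0.34) the MHC class II call. Cell cycle (0.502), oxidative phosphorylation (0.0702), TGF-beta (0.212), immediate-early (0.554), p53 (0.979) and mitochondrially encoded (0.0667) lists, and the erythroid (0.245), B cell (0.408), endothelial (0.618) and mast cell (0.379) lists, did not pass. Oxidative phosphorylation and mitochondrially encoded lists passed as higher without aged control 2 (0.0394 and 0.0427), aged control 3 (0.00894 and 0.00728), replicate 3 (0.00411 and 0.0161) or replicate 4 (0.0002 and 0.00899) of the labelled knockout libraries, and the unfolded protein list as lower without aged controls 1 to 3 (0.0207, 0.0388 and 0.034) or replicate 5 (0.0119). Without replicates 2 and 5 together, the oxidative phosphorylation (camera adjusted p = 0.00183), erythroid (0.0202) and myeloid (0.0369) lists passed as lower. With sex as a covariate, the oxidative phosphorylation (camera adjusted p = 0.0258) and mitochondrially encoded (0.000645) lists passed as higher, and the unfolded protein list (0.0215) as lower. The p53 list was ranked upward by camera with a median of -0.04, and its median was 0.01 with quantile normalization.

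In all, 41 genes rose and 135 fell (176, 1.55%), of which 87 changed at least 2-fold. Fitted with a sex covariate, 61 rose and 178 fell, which is also the comparison of letter C with letter B. The count was 91, 99 and 113 without aged controls 1, 2 and 3, and 116 without replicate 2 of the libraries labelled knockout. Of 41 named calls, 29 held whichever library was left out; 12 were lost in at least 1 omission, most often Calr, Pdia4, Oas1a, Sdf2l1, Csf3r and Gnl3. No gene passed an interaction of sex with this comparison in limma (377 genes at an unadjusted p under 0.05), nor with age (998) or with the comparison to young controls (861).

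Some of these genes set all 5 libraries labelled knockout apart from all 10 controls. The mt-Nd3 gene was at 0 to 0.59 FPKM in them and at 11.14 to 24.19 in controls. Gm28438 (chromosome 1, 24612775 to 24613119), a nuclear copy of mt-Nd3 that differs from it at 1 of 345 aligned bases, went the opposite way, with 16.66 to 51.47 FPKM in them and 0 to 0.64 in controls. The 2 values summed were 31.1 ± 14.5 FPKM in the libraries labelled knockout and 18.6 ± 5.14 in aged controls (SD, n = 5 each). The reads of this pair are therefore uncertain as to their gene. Gm28438 was named after its values were seen. Around Thbs1, 9 of 82 tested genes within 5 Mb passed the test against aged controls, against 167 of 11263 elsewhere (odds ratio 8.19, Fisher's exact two-sided p = 4.7e-06; 2.08e-06 within 10 Mb and 1.39e-07 within 20 Mb). Against young controls 8 of 82 passed (Fisher's exact p = 5.47e-05). With age the same region held 9 of 82 (odds ratio 2.7, Fisher's exact p = 0.00995, 0.0405 within 10 Mb and 0.733 within 20 Mb), a comparison that does not involve the knockout label. After this was seen, genes changed the same way against both control groups were counted: 7 of 82 within 5 Mb and 19 of 11263 elsewhere (odds ratio 55.1, Fisher's exact p = 4.68e-10). They were Tmem87a (120355312 to 120404113) and, likewise higher, Gatm and Itpka (0.82), and Slc28a2 (-1.28; 122426477 to 122461137), Spata5l1 (-1.27), Sord (-1.12) and Snap23 (-0.88), which were lower. Sord, Slc28a2, Gatm and Spata5l1 lie close together, between 122234749 and 122632930. Fisher's test treats genes as independent, so its p-values for this region may be too small. Spint1 (-1.10) and Gm14207 (-1.63), also within 5 Mb, fell against aged controls but not against young controls. Within 10 Mb, 9 of 118 tested genes changed the same way against both control groups, Kcnip3 and Prom2 among them, and within 20 Mb 11 of 208.

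**Figure D3:**
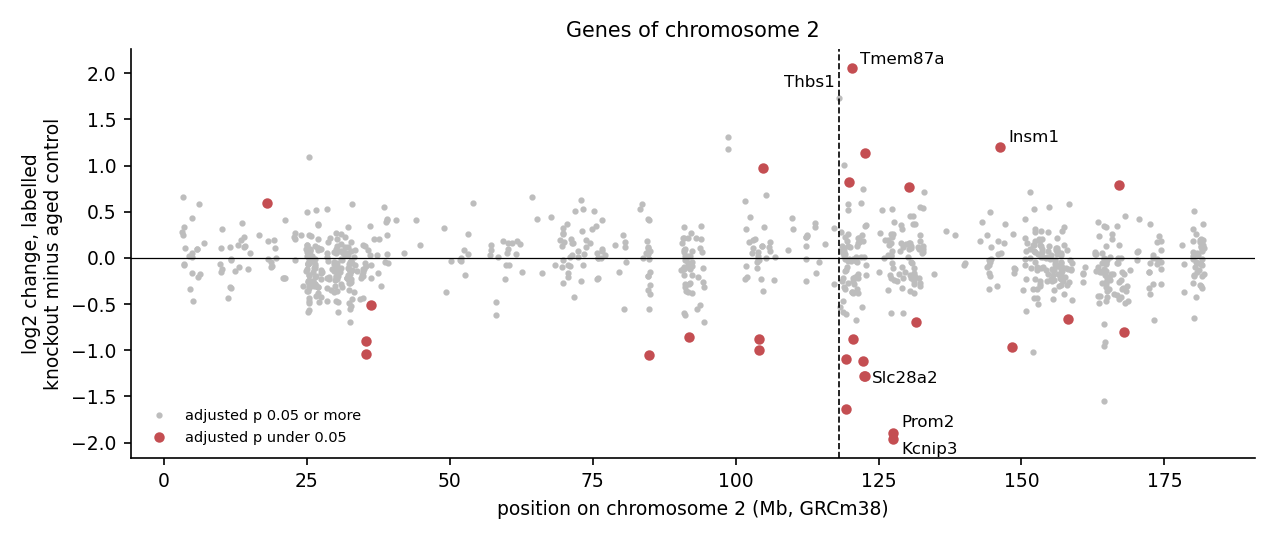
Log2 change of each tested gene of chromosome 2, libraries labelled knockout minus aged controls, by position in Mb (GRCm38); red points passed the test and the dashed line marks Thbs1. Within 5 Mb of Thbs1, 9 of 82 tested genes passed.

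The third comparison set the libraries labelled aged Thbs1 knockout against young controls, to ask how far they lay from the young level; here too Thbs1 was not lower. Many age-related genes stayed higher. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, rose by 2.46 (SE 0.23, limma adjusted p = 5.68e-06) and 2.12 (SE 0.27, adjusted p = 0.000327), with Mt1 going from 28.1 ± 6.58 to 167 ± 82.0 FPKM (SD, n = 5 each). Cldn5 rose from 2.96 ± 0.409 to 18.6 ± 7.80 FPKM (log2 change 2.24, adjusted p = 0.00315) and Gpr183 from 0.964 ± 0.279 to 7.20 ± 4.75 FPKM (log2 change 1.89, adjusted p = 0.00443). The secreted peroxidase gene Gpx3 rose (adjusted p = 0.0102), Cytl1 by 2.22, the receptor-modifying gene Ramp2 by 2.18, Matn4 by 2.09, Zg16 by 1.96 and Tmem87a by 1.91. The gene mt-Nd3 fell by 3.53 (adjusted p = 1.73e-09), while its sum with the near-identical nuclear copy Gm28438 went from 14.1 ± 2.43 to 31.1 ± 14.5 FPKM (SD, n = 5 each), and 2 neighbours of Thbs1, the nucleoside transporter gene Slc28a2 and Spata5l1, fell by 2.04 (adjusted p = 6.53e-07) and 1.98. Ppbp fell from 18.0 ± 6.40 to 3.97 ± 1.51 FPKM (log2 change -1.92, adjusted p = 0.00455), and the melanocortin receptor gene Mc5r by 1.74 (adjusted p = 0.00736). Rnase6 (-1.43), Kcnip3 (-1.41), the cation transporter gene Slc22a3 (-1.41), Antxr2 (-1.37) and Hnf4a (-1.33) were also lower.

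Of 32 HSC aging genes, 10 rose and none fell against young controls (19 rose and 1 fell adjusted over the list alone; median 0.62, camera adjusted p = 2.59e-15, and adjusted p = 0.0687 with an estimated correlation), among them Clu (1.57) and Tm4sf1 (1.74). Of 34 cell cycle genes, 3 fell (26 fell and 1 rose adjusted over the list alone; median -0.66, camera adjusted p = 2.28e-10, and 0.41 with an estimated correlation): Top2a (-0.97), the ribonucleotide reductase gene Rrm2 (-0.94) and Pcna (-0.85). A pseudogene that differs from Pcna at 6 of 781 aligned bases was higher in every library labelled knockout, and reads were not traced between the 2, so the fall of Pcna is uncertain. Of 11 lymphoid priming genes, Cd27 (-0.61) fell (4 adjusted over the list alone; camera adjusted p = 0.00173, and 0.0601 with an estimated correlation). No ribosomal protein gene passed over all genes, while 60 of 64 rose adjusted over the list alone (median 0.75, or 0.36 with quantile normalization; camera adjusted p = 9.44e-30, and 0.41 with an estimated correlation). Without replicates 2 and 5 of the labelled knockout libraries, which had the highest scores of this list (9.26 and 9.48), the median was 0.31 and the camera adjusted p 2.4e-14; replicates 3 and 4 (8.12 and 8.16) lay within the young range (7.73 to 8.21). Oxidative phosphorylation genes (camera adjusted p = 0.0001, and 0.623 with an estimated correlation) and 9 mitochondrially encoded genes (0.0314, and 0.623 with an estimated correlation; 7 rose and 1 fell adjusted over the list alone) lay higher; without replicates 2 and 5 of the labelled knockout libraries these were 0.858 and 0.294. The mitochondrial list also did not pass without young control 4 (0.0667), young control 5 (0.0548), or replicate 1 (0.0755) or 2 (0.166) of the labelled knockout libraries, and the MHC class II list passed as higher without replicate 4 (0.018). Other members past the test were Socs3 (0.75), Ccl5 (-1.08), Bmp4 (1.04), Selp (1.23), Prtn3 (0.91), Mycn (-0.65) and the globin gene Hbb-bt (-1.14), in lists that did not pass the camera test. Median and mean differed in sign for the HSC identity (-0.08 and 0.01), TGF-beta (-0.05 and 0.01), myeloid (-0.12 and 0.03) and mast cell (-0.06 and 0.09) lists, and camera ranked the thrombospondin (median -0.13) and lysosome (-0.04) lists upward.

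In all, 115 genes rose and 70 fell against young controls (185, 1.63%), of which 86 changed at least 2-fold. When sex was a covariate 224 rose and 205 fell, which is also the comparison of letter C with letter A; with quantile normalization that split was 395 and 238. The count of 185 became 668 without replicate 4 and 492 without replicate 3 of the libraries labelled knockout. It became 98, 123, 103, 114 and 98 without young controls 1 to 5. Of 33 named calls, 23 held whichever library was left out; 10 were lost in at least 1 omission, most often Prtn3, Rrm2, Top2a, Bmp4, Slc22a3 and Socs3.

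The change with age and the change with the knockout label were set against each other to ask whether the labelled knockout libraries lay nearer to young controls. Of the 361 genes that rose with age, 96 fell in the libraries labelled knockout against aged controls, and 216 fell when adjusted over the list alone. Cldn5, Gpr183, Muc1 and Rcvrn all had log2 changes of opposite sign. The median of these 361 genes was 0.96 with age, -0.54 against aged controls and 0.44 against young controls, and 74 of them still passed the test against young controls. Of the 140 genes that fell with age, 12 rose in the libraries labelled knockout, Ebi3 among them. Another 2, the Thbs1 neighbours Slc28a2 and Spata5l1, fell further against aged controls. The aged controls enter both comparisons, which alone gives opposite signs: 334 of the 361 genes (92.5%) had the opposite sign, against 89.7% when unchanged groups were simulated against shared controls, and 125 of the 140 (89.3%), against a simulated 93%. Across all 11345 genes, which are not independent replicates, the changes correlated at -0.455 (simulated -0.5), with a covariance of -0.0551 (simulated -0.0209). The simulated groups held no change with age, and their genes were ranked by noise alone. The simulated shares and correlation are therefore not a baseline for genes that did change with age. With the aged controls split into 2 and 3 libraries, so that none was shared, the mean correlation was -0.265 over 20 splits (range -0.483 to 0.244) and the mean covariance -0.0343. With the sex term removed, a setting chosen after seeing the data, the mean correlation was -0.276 (range -0.456 to -0.089). Under a sex covariate 108 of the 361 genes fell, and 108 without replicates 2 and 5 of the labelled knockout libraries.

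**Figure D4:**
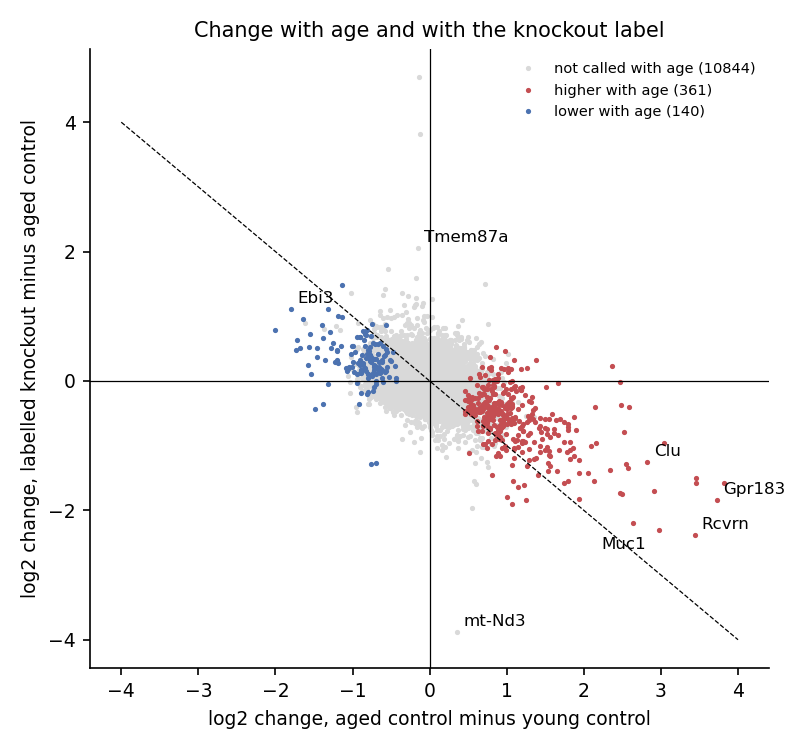
Log2 change of each tested gene with age (horizontal) and between the libraries labelled knockout and aged controls (vertical); red points rose and blue points fell with age, and the dashed line marks equal changes of opposite sign. Of 361 genes that rose with age, 334 lay below 0 on the vertical axis, where simulated unchanged groups with shared controls gave 89.7%. The simulated genes were ranked by noise alone, so this share is not a baseline for genes that did change with age.

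The last comparison asked how 8 female libraries differed from 7 male libraries over all groups. Its genes were chosen after their values were seen. A batch that followed replicate number cannot be told apart from sex here, since males carried the lower numbers in every group. Myl10, a myosin light chain gene, averaged 265 FPKM in female and 22.3 in male libraries (log2 change 3.21, SE 0.33, limma adjusted p = 4.06e-05). The monocarboxylate transporter gene Slc16a12 (1.73), Bace2 (1.71), Slc13a2 (1.55), Ern1 (1.36), an endoplasmic-reticulum stress sensor, and the X-linked gene Eif2s3x (1.19) were also higher in female libraries. The transcription factor genes Gfi1 (-1.11) and Lmo1 (-0.97) and the enzyme regulator gene Gchfr (-1.10) were lower. Of 9 MHC class II genes, Cd74 (-0.94), H2-Aa (-0.77), H2-DMb2 (-0.70) and H2-Oa (-0.57) were lower in female libraries (7 adjusted over the list alone; camera adjusted p = 3.48e-05, and 0.66 with an estimated correlation). Of 21 immediate-early genes 5 were lower, among them Egr1 (-0.89), Jund (-0.74), Fosb (-0.60) and Ier2 (-0.56), with 6 lower adjusted over the list alone (camera adjusted p = 0.000575, and 0.66 with an estimated correlation). Mitochondrially encoded (0.000608, and 0.682 with an estimated correlation), ribosomal (6.5e-05, and 0.783 with an estimated correlation) and oxidative phosphorylation lists (0.0314, and 0.783 with an estimated correlation) lay lower. The HSC aging list did not differ (adjusted p = 0.811). In all, 699 genes were higher and 209 lower in female libraries (908, 8%); with quantile normalization the split was 584 and 331. The count ranged from 173 without aged control 3 to 3035 without young control 1, was 2455 without replicate 5 of the libraries labelled knockout, and moved by more than 1.5 times in 14 of 15 omissions, all but that of young control 2.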

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

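Chosen after the results were seen were the tests of mt-Nd3 and its nuclear copy, of the other mitochondrial genes, of the neighbours of Thbs1, of platelet genes, of the libraries without replicates 2 and 5, of the Thbs1 mean and of medians over splits of the aged controls; sex as a covariate and the counts over other splits of the samples were planned. A value was set apart when its gap to the nearest other library of its group was large against the range of the group (Dixon's 95% critical value for 5 values). Of 342 groups of 5 values tested, 26 (7.6%) held such a value, where chance gives about 1 in 20, or 17.1.

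Replicate 5 of the libraries labelled aged Thbs1 knockout stood apart most often: Mt2 was at 24.05 FPKM (6.18 to 7.41 in the other 4), Nupr1 at 75.62 (26.21 to 30.92), Plscr2 at 18.61 (3.86 to 5.9), Tmem215 at 2.7 (0.32 to 0.76), Snhg1 at 29.8 (12.46 to 16.08) and Itga2b at 17.61 (38.26 to 50.95). Replicate 2 of that group had Kcnip3 at 0.83 FPKM (3 to 3.43) and an HSC identity score, the mean log2(FPKM + 1) of the list, of 4.93 (5.05 to 5.09), and replicate 3 a lymphoid priming score of 3.12 (2.87 to 2.93). Aged control 5 lay nearer to young controls in Gpr183 (12.33 FPKM against 26.01 to 32.78) and Procr (60.87 against 109.46 to 133.2). It lay above its group in the proliferation genes Rrm2 (42.32 against 15.86 to 17.96), Top2a (4.43 against 2.39 to 2.67) and Chek1 (2.11 against 0.57 to 0.88). Aged control 4 was low in Itga2b (63.43 FPKM against 144.52 to 192.13), Ly6a (240.63 against 285.9 to 306.15) and the oxidative phosphorylation score (6.48 against 6.79 to 6.91), and aged control 2 in Col18a1 (7.58 FPKM against 12.85 to 14.91). In young controls, replicate 4 was high in Bcl3 (13.84 FPKM against 8.5 to 9.18) and replicate 2 in Ebi3 (51.88 against 42.42 to 44.2), replicate 2 was low in Mc5r (11.56 against 18.45 to 20.72) and Ramp2 (2.21 against 2.97 to 3.31), replicate 3 in Rrm2 (27.19 against 33.49 to 35.37), and replicate 1 in Mt2 (0.73 against 1.32 to 1.46). Replicate 5 was low in the interferon score (3.98 against 4.15 to 4.21) and replicate 1 in the lysosome score (4.56 against 4.65 to 4.68). No test of these single values against a cause was made.

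Over splits of the same libraries into groups of the same sizes (100 for each comparison, the real one counted among them), only the real one gave the 501 genes of aged against young controls (1 of 100), and the highest other gave 292. Chance is unlikely there, though 100 of the 126 possible splits were counted and 1 of 100 is the smallest share they can give. For the libraries labelled knockout against aged controls, 5 of 100 gave at least the real 176, so chance cannot be excluded. The highest other, 2521 genes, parted all 5 male from all 5 female libraries. That points to a structure by sex or by a batch that ran with sex. With sex as a covariate (letter C against letter B) 2 of 100 gave at least the real 239. Chance is less likely there but not excluded, since the highest other split gave 358, more than the real one. That split put replicates 2 and 5 of the labelled knockout libraries with aged controls 1 to 3. Against young controls 2 of 100 gave at least the real 185 (highest other 862, young controls 1, 3 and 5 with replicates 3 and 4 of the labelled knockout libraries); with sex as a covariate 1 of 100 did (real 429, highest other 1). For letter B against letter A 1 of 100 did (real 625, highest other 1), and for female against male libraries 1 of 100 (real 908, highest other 0).

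Thbs1 was not lower in the libraries labelled aged Thbs1 knockout. Columns mixed up between single labelled knockout and control libraries were not excluded. When mt-Nd3 was set against its nuclear copy, 0 libraries lay on the wrong side, but this pair was picked after it was seen to part these groups. That count cannot decide this, nor whether whole groups carry the wrong title. A mix-up between young and aged controls is argued against by the HSC aging list, fixed beforehand. Its mean log2(FPKM + 1) was 2.8 to 3.06 in young controls and 4.26 to 4.63 in aged controls. The larger number of female libraries in this group is argued against as the whole cause, since the difference was still 1.27 on the log2 scale with sex as a covariate. Reads of a transcript that a targeted allele still makes cannot be told apart from reads of an intact gene, because the mean of 10.4 FPKM is a value per gene with no exon values. A biological rise of Thbs1 in these mice was not tested.

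Several genes set all 5 libraries labelled knockout apart from all controls. A lower yield of mitochondrial RNA is argued against for mt-Nd3, since the other mitochondrial protein genes had a median log2 change of 0.66. A mitochondrial variant that sends mt-Nd3 reads to the nuclear copy Gm28438 is consistent with the copy's 16.66 FPKM or more in each of these libraries, against at most 0.64 in a control. DNA of another strain around Thbs1, carried along with a targeted allele, may explain the 7 neighbours changed against both control groups (Fisher's exact p = 4.68e-10, in a count chosen after a first count had also been raised with age). That p treats neighbouring genes as independent and may be too small. An effect of the Thbs1 allele on its neighbours stays open and was not tested.

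Genes that rose with age lay lower in the libraries labelled knockout. Replicates 2 and 5, which stand apart, are argued against as the cause, since the median log2 change of these genes was -0.59 without both. The aged controls shared by both comparisons cannot be told apart from a change of these genes: over splits of the aged controls the highest median was 0.09, with the sex term removed it was -0.13, and for genes that fell with age the medians ran from -0.09 to 0.22 even then. The HSC aging list was fixed beforehand, so its genes were not picked through these controls. Its mean log2(FPKM + 1) was 3.24 to 4.15 in the labelled knockout libraries and 4.26 to 4.63 in aged controls (camera adjusted p = 1.1e-16, and 0.0663 with an estimated correlation). For the genes of this list, that argues against the shared controls as the whole cause. Megakaryocyte or platelet cells in the aged control samples cannot be told apart from a change of the age genes. Platelet genes outside the aging list had a median change of only 0.11 with age, while 14 of 15 were lower in the libraries labelled knockout (median -0.40, against -0.54 for the genes that rose with age). A knockout effect, a difference in strain background elsewhere in the genome and other differences between the mice stay open as untested. Chance is not excluded for the count of 176 genes, which ignores sex (5 of 100 splits, the real one among them, gave as many). It is less likely, but not excluded, for the 239 with sex as a covariate (2 of 100, with 358 in the highest other split).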

How the results depend on the processing

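Chosen after seeing the data were voom, the grouping by GEO's descriptions, leaving out replicates 2 and 5 of the libraries labelled knockout, the share of rRNA-like reads as a covariate, each sex alone, the block with a sex covariate, the group covariate in the comparison of sexes, the list tests with 1 library left out and the splits with the sex term removed. Where no cause is given below, the cause was not tested. Pseudocounts of 0.1 and 5, both scalings and robust eBayes moved no total count of genes by more than 1.5 times, but quantile normalization moved the higher genes from 115 to 189 for the labelled knockout libraries against young controls and from 224 to 395 for letter C against letter A, and the lower genes from 209 to 331 for the sexes. These settings moved the median of all genes by less than 0.1 on the log2 scale.

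With age, 501 genes were called, 265 at a mean FPKM of 5 or more (fewer genes tested), 5397 with array weights, 1020 with only the 2 groups, 1066 in male and 22 in female libraries (each with 5 libraries of these 2 groups), 1035 without replicates 2 and 5 of the labelled knockout libraries and 993 with the rRNA-like share as a covariate. For the labelled knockout libraries against aged controls, 176 genes became 113 with the higher filter, 3688 with array weights, 77 with only the 2 groups and 10 in female libraries. Against young controls, 185 became 120 with the higher filter, 475 with array weights, 429 with sex as a covariate, 853 in male and 11 in female libraries, 119 without replicates 2 and 5 and 109 with the rRNA-like share.

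In the fits of letters, which hold sex as a covariate, the 625 genes of letter B against letter A became 336 with the higher filter, 1471 with array weights, 1434 without replicates 2 and 5 of the labelled knockout libraries and 1121 with the rRNA-like share. The 239 of letter C against letter B became 548 with array weights and 155 with the rRNA-like share. The 429 of letter C against letter A became 257 with no filter, 185 with no sex covariate, 272 without replicates 2 and 5 and 151 with the rRNA-like share. The 908 of female against male libraries became 411 with no filter, 5696 with array weights and 1468 with group as a covariate.

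Grouping the columns by the library names in GEO's descriptions gave 0 genes with age in limma (642 at an unadjusted p under 0.05), 0 for knockout against aged controls (731) and 15 for knockout against young controls. Of 124 named calls, 0 stayed and 88 turned sign, 49 of 50 with age; they are given only as this count, since 10 of 15 libraries then change their group. This grouping puts aged controls 1 to 3 with young controls 1 and 2. The mean log2(FPKM + 1) of the HSC aging list, fixed beforehand, was 2.8 to 3.06 in libraries titled young control. It was 4.26 to 4.63 in those titled aged control, which argues against this grouping for young and aged controls. No named gene reversed under any alternative other than this grouping. The difference of Thbs1 from aged controls kept its direction, with 3.28 under array weights (adjusted p = 0.000622) and 1.27 with sex as a covariate (0.0377); only these 2 alternatives passed the test, and adjusted p over all alternatives ranged from 0.000622 to 0.934 (female libraries alone). The difference was 1.39 without aged control 2 to 2.21 without aged control 4.

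Replicate numbers did not pair the libraries throughout. The 15 pairs of libraries with the same number correlated at -0.455 to 0.527, 6 of them over 0.1, and in 5 of the pairs the library with its own number correlated best. These were replicate 2 in all 3 pairs of groups (0.489, 0.372 and 0.47), and replicates 1 and 4 between aged controls and labelled knockout libraries (0.341 and 0.527). Some structure by replicate number is therefore not excluded. With the replicate block 499, 152 and 158 genes were called in the 3 comparisons of groups, and with the replicate block and a sex covariate 270, 112 and 211.

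Leaving out 1 library gave 302 (without aged control 1) to 931 (without aged control 5) genes with age, 91 (aged control 1) to 225 (aged control 5) against aged controls and 98 (young control 1) to 668 (labelled knockout 4) against young controls. In the fits of letters the ranges were 372 (young control 1) to 802 (aged control 5), 119 (labelled knockout 2) to 341 (labelled knockout 5) and 165 (young control 1) to 1267 (labelled knockout 4), and for the sexes 173 (aged control 3) to 3035 (young control 1). Of 124 named calls, 89 held in every omission. Named calls lost were 98 in female libraries alone, 21 with only the 2 groups, 20 with no filter, 16 in male libraries alone, 13 without replicates 2 and 5 of the labelled knockout libraries, 11 with the block, 9 with the rRNA-like share, 6 with voom, 5 each with quantile normalization and a pseudocount of 5, and at most 3 with each other setting.

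Of 66 list tests, 22 lost and none gained a call with an estimated correlation, and fry lost 13 and gained 3. With sex as a covariate 2 list calls were lost and 3 gained. Over all omissions of 1 library, 31 list calls were lost, 13 gained and none reversed. Without replicates 2 and 5 of the labelled knockout libraries, 2 list directions reversed: oxidative phosphorylation lay lower against aged controls (adjusted p = 0.00183) and did not differ from young controls (0.858). In this setting 3 other list calls were lost and 3 gained. Gained as lower were the erythroid list against aged (camera adjusted p = 0.0202) and young controls (0.0129), and the myeloid list against aged controls (0.0369). The correlation of the 2 changes was -0.265 with split controls, where none is shared, and -0.685 without replicates 2 and 5. Planned fits with the letter, with sex and letter, or with group added to the letter were not run, because letter and group coincide. Genes under a mean FPKM of 1 were not tested, and in simulated reads a 1.5-fold change was recovered for 25.4% of simulated genes with age and 20.9% in the other comparisons.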

Other observations

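The test here was chosen after the result was seen. Besides Gm28438, 2 processed pseudogenes passed the test against both control groups and were higher in every library labelled aged Thbs1 knockout than in every control. Pcna-ps2 (chromosome 19, 9283380 to 9284160) lay at 18.51 to 33.36 FPKM in these libraries and 0.44 to 1.36 in controls. It matches Pcna at all but 6 of 781 aligned bases, and Pcna lies 14.1 Mb from Thbs1. Gm7658 lay at 1.96 to 2.73 FPKM against 0.21 to 0.93, and matches Eif3m, 13.1 Mb from Thbs1, at all but 16 of 1125 aligned bases. Variants of another strain in parent genes around Thbs1 may have sent reads to these copies. The binomial chance that both parents lie within 20 Mb of Thbs1 was 0.000336, with only 2 pseudogenes to test. Eif3m did not fall with this (46.23 to 77.3 FPKM in the libraries labelled knockout, 37.7 to 66.57 in controls), while Pcna ranged from 37.49 to 60.16 FPKM against 48.9 to 101.42.

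Over the whole table, 26 genes changed the same way against both control groups. Within 5 Mb of Thbs1 lay 7 of them, and at most 2 within 5 Mb of any of the 11227 tested genes on other chromosomes or more than 10 Mb from Thbs1; genes nearer to Thbs1 were not counted in this. Pf4, an abundant platelet chemokine gene, averaged 251 FPKM in young controls, 548 in aged controls and 136 in the libraries labelled knockout, and its log2 change of 0.60 with age did not pass the test (limma adjusted p = 0.472).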
